A study of Mus musculus with 54 samples.

How the data were processed

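The series holds 54 two-colour Agilent arrays of RAW264.7 macrophage RNA against a commercial universal mouse reference RNA, from 27 cultures measured with both dye orientations. The 8 groups are media, LPS, poly(I:C) and CpG at 6 and 24 h. Per the labels the replicates are separate cultures and RNA isolations, and media at 24 h has 6 cultures where the design text states 3. The replicate numbers were not treated as pairs. The arrays were scanned on 6 days with 2 scanners, and LPS and media of 24 h shared no day.

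The deposited scanner files hold spot signals and backgrounds as intensity in scanner units, extracted with Feature Extraction 8.1.1.1 per the file headers. The scanner software's ratio in the deposited files is a log10 ratio of Cy5 over Cy3 after its own dye normalisation. The deposited flags of spots, for saturation, outliers and signal well above background, are other values coded 0 or 1. The value table from the authors holds a log2 ratio of cells over reference for 20818 probes. Its absolute correlation with the scanner ratio ran from 0.739 to 0.989 between arrays, and the authors' normalisation is unstated.

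Each array has 22393 spots, of which 1075 are controls, and 20868 probes. Probes were named from a table of RefSeq genes, 13969 by RefSeq accession, 2385 by symbol and 2255 by synonym, and 2259 kept the name in the file. The analysis was run in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. Signals were background corrected by normexp with an offset of 50, and log ratios were normalised within each array by loess with zero weight for controls. Spots marked by the scanner software as outliers, 1.80 to 60.9% of an array, were set to missing. A culture's value was the mean of both orientations. With 1 orientation missing, the other was corrected by the mean dye effect of the probe. The brightest probe was taken for the 1254 genes with several. Genes had to stand well above background on both arrays of at least 3 of the 27 cultures, which left 18892. Of their values in cultures 64.4% came from both arrays and 23.0% from 1 array, and 12.6% were missing.

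The median cell signal of an array was 179.6 to 1792 intensity units (median 586.7) and that of the reference 347.7 to 3882. With these group sizes, tests on simulated data recovered 87.5 to 95.5% of log2 changes of 1 and 98.8 to 100% of changes of 2, all with the right sign. The 6 to 12 false calls leave out effects of scan day. The highest correlation between any pair of arrays was 0.9941, so no array was a copy of another.

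All 8 groups were fitted together with limma, and 16 contrasts were tested: each ligand against media at each time, the ligands against each other, the difference of each response between times, and media over time. A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05. A gene was tested in a contrast where each of its groups had a value in at least 2 cultures. This rule was set after counts under a stricter one, a value in all 8 groups, had been seen, because that one left out Il1b, Ptgs2, Ifit1 and Irf7. It left 14533 genes tested in every ligand comparison and 551 in none.

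The contrasts, 10 genes of the innate response and 18 gene lists were fixed before the data were examined, and so was the rule for naming the 10 largest rises and 6 largest falls without overlap between cultures. By chance 10% of genes have no overlap between groups of 3. The lists were interferon-stimulated genes, inflammatory cytokines, chemokines, NF-kB subunits and feedback regulators, pattern receptors, antigen presentation, inducible effector enzymes, immediate-early genes, cell cycle, apoptosis, cholesterol and fatty acid metabolism, glycolysis and hypoxia, respiratory chain, lysosome and macrophage identity, endoplasmic reticulum stress, heat shock proteins, osteoclast genes and markers of other cell types. They were tested with camera at a preset correlation of 0.01, adjusted over 108 tests for the ligand comparisons, and again with the correlation estimated. A call that ended with the estimated correlation is given with that adjusted p. The test fry, of whether a list moves on balance in 1 direction, was run beside it. List members absent from the array included Oas1a, Xaf1, Phf11, Ccl9, Cxcl3, Dusp2, H2-D1, Psme2, Bcl2a1a, Gapdh, Psat1 and Hbb-bt.

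Alternatives listed beforehand covered background, normalisation, the scanner and authors' ratios, the macrophage channel alone, 1 dye orientation, filters, probe summary, the fit, blocks of replicate and scan day, thresholds, the media sets of 24 h and leaving out each culture. Chosen after the data had been seen were keeping outlier spots, leaving out the departing array of poly(I:C) replicate 2 at 24 h, both together, culture values from both arrays only, genes measured in all 8 groups, fits within 1 scan day, shared genes with scan day as a block, and all settings for the lists of the time differences. The fixed block of scan day was fitted to single arrays, with a correlation of -0.141 between the arrays of a culture. That weighs them as more than independent values, so its counts are not on the same footing as those from culture values. Fits within 1 scan day split every group by the day of the Cy3 array and took the spread from all cultures. For counts each comparison was also repeated with its cultures split into groups of the same sizes in every other way. For differences between times 100 drawn ways were used.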

Results

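RAW264.7 cells, a mouse macrophage line, were kept in media or given 1 of 3 ligands of Toll-like receptors, and RNA was taken after 6 and 24 h. Lipopolysaccharide (LPS), an outer-membrane component of Gram-negative bacteria sensed by Tlr4, was given at 0.5 µg/ml. Poly(I:C), a synthetic double-stranded RNA sensed by Tlr3 and by helicases of the cytoplasm, was given at 0.25 µg/ml. CpG DNA, an oligonucleotide sensed by Tlr9, was given at 1.5 µM. The doses are of different molecules and cannot be matched, so sizes of response compare these doses and not the receptors. There were 27 cultures, 3 in each group and 6 in media at 24 h. Each was measured against a common reference RNA on 2 arrays with exchanged dyes, 54 in all.

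The median cell background of an array was 45 to 60 intensity units, and 89.8 to 98.6% of spots stood well above background. The log ratios of the array pair of a culture had a correlation of 0.780 to 0.947, except for poly(I:C) replicate 2 at 24 h, where it was 0.117 and log2 values without the departing array are given below. The 6 media cultures at 24 h formed a pair of sets, replicates 1 to 3 and 4 to 6, between which 2319 of 12106 genes differed. Changes are log2 fold changes ± standard error, from 3 cultures a group and 6 in media at 24 h unless n is given. Genes were called at adjusted p under 0.05. The largest rises and falls were taken among called genes in which no culture of 1 group overlapped the other. For gene lists the brackets give members called, the number called when adjusted over the list alone (by list), the mean change and the adjusted p of the set test camera.

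After 6 h LPS raised genes of inflammation and of the interferon response. Csf3, the growth factor of neutrophils, rose by 5.85 ± 0.21 (57.6-fold, adjusted p = 5.3e-16), with a log2 ratio over the reference of 5.48 ± 0.19 against -0.37 ± 0.08 in media. Cxcl10, which draws activated T cells, rose by 5.53 ± 0.46 (46.2-fold) and Cmpk2, an interferon-induced nucleotide kinase, 4.95 ± 0.40. The acute-phase gene Saa3 rose by 4.81 ± 0.16 (28.0-fold, adjusted p = 2.0e-16), the cytokine Il1a 4.58 ± 0.18, the chemokine Ccl3 4.50 ± 0.80 (adjusted p = 0.00034, n = 2 and 3) and Il10, which restrains inflammation, 4.17 ± 0.16. The largest falls were of Rasa3, which restrains Ras, -2.18 ± 0.10 (4.52-fold, adjusted p = 2.2e-12), N4bp2l1 -1.90 ± 0.16, the transcription factor Lyl1 -1.77 ± 0.23 and the fatty acid desaturase Scd2 -1.66 ± 0.27 (n = 2 and 3). Of the genes chosen beforehand, Tnf rose by 2.82 ± 0.52 (adjusted p = 0.0011, n = 2 and 2), Nos2, which makes nitric oxide, 2.07 ± 0.46 (adjusted p = 0.0034, n = 2 and 3) and Il6 1.04 ± 0.13 (adjusted p = 2.8e-06). The interferon regulator Irf7 rose by 2.75 ± 0.43 (adjusted p = 0.00014) and the chemokine Ccl5 3.04 ± 0.44 (adjusted p = 2.4e-05). Csf1r, the receptor for the macrophage growth factor, fell, at -1.40 ± 0.14 (adjusted p = 8.2e-08). Il1b, Ptgs2, the inducible cyclooxygenase, and Ifit1 had too few cultures after outlier spots were removed, and with those kept rose by 6.58 ± 0.15, 6.15 ± 0.24 and 2.39 ± 0.22. Csf3 stood well above background on only 4 of 6 media arrays, the scanner software ratio put Il6 at log2 2.57 and the macrophage channel alone put Nos2 at 3.61.

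By gene list, LPS at 6 h raised interferon-stimulated genes (21 of 25 up, 23 by list, mean 2.15, adjusted p = 2.9e-56). Usp18, which removes the interferon-induced tag Isg15, rose by 3.98 ± 0.30 (n = 2 and 3) and Ifit3 by 3.88 ± 0.25. It raised inflammatory cytokines (12 up and 1 down of 21, 13 and 1 by list, mean 1.55, adjusted p = 1.2e-38). Chemokines rose (9 up and 0 down of 13, 10 and 1 by list, mean 2.5, adjusted p = 1.9e-38). Ccl22, which draws regulatory T cells, rose by 3.92 ± 0.12. NF-kB subunits and feedback regulators rose (13 of 20 up, 14 by list, mean 1.19, adjusted p = 7.1e-29). Nfkbiz, an IkB protein of the nucleus, rose by 3.82 ± 0.14 (n = 2 and 3) and Zfp36, which destabilises cytokine mRNA, 3.15 ± 0.15. Inducible effector enzymes and secreted proteins rose (12 of 25 up, 13 by list, mean 0.94, adjusted p = 1.2e-13). Lcn2, which withholds iron from bacteria, rose by 3.24 ± 0.39. Antigen presentation and costimulation genes rose (5 up and 0 down of 20, 10 and 2 by list, mean 0.63, adjusted p = 3.9e-05). The peptide transporter Tap1 rose by 3.09 ± 0.27 (n = 2 and 3). Apoptosis and survival genes rose (8 up and 1 down of 18, 9 and 2 by list, mean 0.48, adjusted p = 1.7e-05), and Gadd45b rose by 2.68 ± 0.21. Immediate-early and AP-1 genes rose (5 of 14 up, 5 by list, mean 0.56, adjusted p = 0.00056), a call that ended without media replicate 1 (mean 0.39). Pattern receptors rose (5 up and 1 down of 21, 5 and 1 by list, mean 0.33, adjusted p = 0.033, 0.1 with an estimated correlation). Tlr3 rose by 2.45 ± 0.16. The list call ended without media replicates 1 or 2 (0.28 and 0.32) or LPS replicate 3 (0.31).

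LPS at 6 h lowered cell cycle and DNA replication genes (4 of 24 down, 5 by list, mean -0.36, adjusted p = 0.002, 0.3 with an estimated correlation). Cholesterol and fatty acid genes fell (4 of 15 down, 5 by list, mean -0.31, adjusted p = 0.001). Among them cyclin Ccne2 fell, at -1.19 ± 0.20, and the sterol exporter Abcg1, at -1.45 ± 0.13. The mean of the cholesterol list was -0.16 with outlier spots kept and its call ended. Markers of other cell types had no call as a list (adjusted p = 0.75), although the muscle gene Des rose by 1.34 ± 0.20 (n = 2 and 3) and the endothelial Cdh5 1.15 ± 0.15. Glycolysis, respiratory chain, lysosome, endoplasmic reticulum stress, heat shock and osteoclast lists were not called (adjusted p from 0.54 to 0.94). In all, LPS at 6 h changed 1590 of 15837 genes, 880 up and 710 down, of which 384 and 72 changed 2-fold or more. With scan day as a block 1407 genes were called, and leaving out 1 culture gave 1085 to 1258.

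After 6 h poly(I:C) raised interferon-stimulated genes and chemokines. Cxcl10 rose by 5.84 ± 0.51 (57.2-fold, adjusted p = 1.5e-08, n = 2 and 3), with log2 ratios over the reference of 6.04 ± 0.51 against 0.20 ± 0.04 in media, and Ccl12, a monocyte chemokine, rose by 5.01 ± 0.12. Ifit3, which blocks viral RNA, rose by 4.72 ± 0.25, Gbp2, which acts against pathogens inside cells, 4.66 ± 0.25, Usp18 4.37 ± 0.27 and the desmosome gene Dsg3 4.17 ± 0.20. The largest falls were of Lhfpl2 -1.76 ± 0.21 (3.38-fold, n = 2 and 2), N4bp2l1 -1.73 ± 0.16, Tmem144 -1.61 ± 0.18 (n = 3 and 2) and Fgd3, which activates Cdc42, -1.34 ± 0.17 (n = 2 and 3). Of the genes chosen beforehand, Ccl5 rose by 3.03 ± 0.44 (adjusted p = 2.6e-05), Nos2 2.70 ± 0.41 (adjusted p = 6.2e-05), Ptgs2 2.08 ± 0.23 (adjusted p = 7.1e-06) and Il1b 1.25 ± 0.13 (adjusted p = 1.2e-06), the last at log2 0.71 in the macrophage channel alone. Tnf rose by 1.6 ± 0.48 (adjusted p = 0.037, n = 3 and 2), a call that ended without any 1 of the poly(I:C) cultures (1.52, 1.58 and 1.70), and Il6 was not called (0.39, adjusted p = 0.056). Csf1r fell, at -0.54 ± 0.14 (adjusted p = 0.011), a call that ended without replicate 3 of media (-0.50) or of poly(I:C) (-0.49) and with scan day as a block (-0.25). With scan day as a block Fgd3 was not called (-0.61) and Tmem144 stood at -1.06. Ifit1 and Irf7 had too few cultures, and with outlier spots kept rose by 2.60 ± 0.22 and 3.40 ± 0.38.

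By gene list, poly(I:C) at 6 h raised interferon-stimulated genes (18 of 21 up, 19 by list, mean 2.25, adjusted p = 4.2e-60) and chemokines (10 of 13 up, 10 by list, mean 2.25, adjusted p = 2.1e-41). Ccl4, which draws monocytes, rose by 3.55 ± 0.60. It raised inflammatory cytokines (6 up and 1 down of 21, 7 and 1 by list, mean 0.60, adjusted p = 3.9e-05). Il1rn, the decoy ligand of the Il1 receptor, rose by 2.75 ± 0.59 (n = 3 and 2). NF-kB regulators rose (8 up and 0 down of 21, 10 and 1 by list, mean 0.57, adjusted p = 2.0e-06). The ubiquitin ligase Peli1 rose by 2.61 ± 0.15. Antigen presentation genes rose (10 of 18 up, 11 by list, mean 0.61, adjusted p = 8.2e-05). Cd40, which receives T-cell help, rose by 2.35 ± 0.27 and Cd274, which restrains T cells, 1.92 ± 0.36. Apoptosis genes rose (8 of 22 up, 9 by list, mean 0.54, adjusted p = 4.6e-08). The death ligand Tnfsf10 rose by 2.35 ± 0.12 (n = 2 and 3). Effector enzymes rose (6 up and 1 down of 27, 7 and 1 by list, mean 0.58, adjusted p = 1.7e-05). Gch1, which makes the cofactor of Nos2, rose by 1.86 ± 0.19. Markers of other cell types rose as well (6 of 20 up, 6 by list, mean 0.35, adjusted p = 0.00044). Des rose by 1.87 ± 0.18 and Cdh5 1.61 ± 0.15. Cell cycle genes fell (4 of 29 down, 5 by list, mean -0.30, adjusted p = 0.0068, 0.41 with an estimated correlation). The other 9 lists were not called (adjusted p from 0.07 to 1.0). In all, 1754 of 16010 genes changed, 988 up and 766 down, of which 369 and 36 by 2-fold or more. The majority turned with the authors' values (1054 up and 1194 down), the scanner software ratio (809 and 818) and the cells in Cy5 alone (690 and 719). No poly(I:C) array shared a scan day with media at 6 h, and with scan day as a block 732 genes were called, of which 577 rose. Leaving out poly(I:C) replicate 1 or media replicate 2 gave 1106 and 1154.

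After 6 h CpG raised a small group of inflammatory genes. Cxcl2, which draws neutrophils, rose by 3.25 ± 0.33 (9.49-fold, adjusted p = 2.5e-06), with log2 ratios over the reference of 5.57 ± 0.40 against 2.32 ± 0.30 in media. The cytokine Il1b rose by 2.93 ± 0.13 (7.62-fold, adjusted p = 1.3e-10), Ptgs2 2.33 ± 0.23 (5.04-fold, adjusted p = 4.2e-05) and Nfkbiz 1.95 ± 0.13 (adjusted p = 5.0e-09). Csf3 rose by 1.87 ± 0.21 (adjusted p = 1.0e-05), Dusp5, which turns off Erk, 1.42 ± 0.22 (adjusted p = 0.0021) and Zfp36 1.11 ± 0.15 (adjusted p = 0.00031). Cebpd, a transcription factor of the acute phase, rose by 1.33 ± 0.24 (adjusted p = 0.0074), a call that ended without CpG replicate 3 (1.21). Among the 7 falls were Rab11fip4, which sorts endosomes, -0.53 ± 0.09 (adjusted p = 0.0028) and N4bp2l1 -0.75 ± 0.16 (adjusted p = 0.028), the latter not called without any 1 of the 6 cultures. Ifit1 rose by 0.74 ± 0.13 (adjusted p = 0.015), but the call ended without media replicates 1 or 3 (0.77 and 0.68) or CpG replicates 2 or 3 (both 0.68). Cxcl10 (0.46), Ccl5 (0.16), Irf7 (0.54), Nos2 (0.35), Il6 (0.20), Csf1r (-0.15) and Tnf (1.51) were not called. In turn adjusted p was 0.88, 0.97, 0.81, 0.91, 0.73, 0.85 and 0.23. Only Il6 and Csf1r of these overlapped media. With outlier spots kept Tnf rose by 1.78 ± 0.40. Csf3 stood well above background on 4 of 6 media arrays, and the scanner software ratio put its log2 change at 3.55.

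By gene list, CpG at 6 h raised inflammatory cytokines (2 of 22 up, 8 by list, mean 0.52, adjusted p = 2.4e-15) and NF-kB regulators (2 of 23 up, 9 by list, mean 0.37, adjusted p = 5.7e-11). Chemokines rose (1 of 15 up, 6 by list, mean 0.71, adjusted p = 8.0e-05), as did effector enzymes (3 of 28 up, 4 by list, mean 0.33, adjusted p = 5.8e-06). Interferon-stimulated genes rose (1 of 37 up, 1 by list, mean 0.31, adjusted p = 3.2e-06, 0.15 with an estimated correlation). Cell cycle genes as a list fell (0 of 31 down, 1 by list, mean -0.23, adjusted p = 0.00053, 0.32 with an estimated correlation). Immediate-early genes rose (1 of 17 up, 2 by list, mean 0.31, adjusted p = 0.00031). Ier3, which modulates survival, rose by 1.07 ± 0.20 (adjusted p = 0.018, n = 2 and 2). The list call ended without replicate 1 of media (0.17) or replicates 1 or 2 of CpG (both 0.20). The other 11 lists, markers of other cell types among them (adjusted p = 0.71), were not called. CpG at 6 h changed 66 of 17538 genes, 59 up and 7 down, of which 21 and 1 by 2-fold or more. A fit with every group split by scan day called 234 genes from the same 6 cultures with the same changes. Only its estimate of spread, taken within days over all groups, was different. With scan day as a block, fitted to single arrays, 472 were called, of which 346 rose. Leaving out media replicates 1 or 3 gave 31 and 41. Of the 10 splits of these 6 cultures into equal groups 2 gave at least as many genes, with 107 in the highest other.

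After 24 h LPS raised effector enzyme, chemokine and interferon genes and lowered respiratory chain genes and Csf1r. Saa3 rose by 5.88 ± 0.14 (59.0-fold, adjusted p = 2.1e-19), with log2 ratios over the reference of 6.14 ± 0.15 against 0.26 ± 0.09 in media. Lcn2 rose by 5.61 ± 0.33, Csf3 5.29 ± 0.18, the chaperone Hspa1a 4.43 ± 0.19 (adjusted p = 1.2e-13), Cxcl10 4.13 ± 0.39 and Cxcl2 4.03 ± 0.28. The largest falls were of the intermediate filament Vim -3.54 ± 0.41 (11.7-fold, adjusted p = 4.6e-07), the urokinase Plau -3.3 ± 0.16 (n = 3 and 3), Txnip, which limits glucose uptake, -3.13 ± 0.31 (n = 3 and 5), Scd2 -3.10 ± 0.24 (n = 3 and 3) and the leukotriene receptor Cysltr1 -3.10 ± 0.24 (n = 3 and 3). Of the genes chosen beforehand, Csf1r fell, at -2.93 ± 0.12 (adjusted p = 1.3e-14). Ccl5 rose by 3.13 ± 0.38 (adjusted p = 1.0e-06), Nos2 2.27 ± 0.36 (adjusted p = 4.3e-05, n = 3 and 5) and Ifit1 1.99 ± 0.13 (adjusted p = 1.6e-08, n = 2 and 5). Tnf rose by 1.75 ± 0.48 (adjusted p = 0.0073, n = 3 and 2) and Il6 0.38 ± 0.11 (adjusted p = 0.0095). The call of Il6 ended with media replicates 1 to 3 alone (log2 0.27) and that of Tnf with scan day as a random block (1.80). Il1b, Ptgs2 and Irf7 had too few cultures, and with outlier spots kept rose by 4.93 ± 0.13, 5.44 ± 0.20 and 3.80 ± 0.33. Cxcl10 stood well above background on 6 of 12 media arrays, and the authors' values put its log2 change at 6.81.

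By gene list, LPS at 24 h raised effector enzymes (18 up and 1 down of 26, 18 and 1 by list, mean 1.11, adjusted p = 4.1e-12). Interferon-stimulated genes rose (20 of 34 up, 21 by list, mean 0.98, adjusted p = 3.5e-09). Chemokines rose (7 of 14 up, 7 by list, mean 1.25, adjusted p = 5.2e-07), and so did inflammatory cytokines (10 of 20 up, 11 by list, mean 0.87, adjusted p = 1.7e-05). NF-kB regulators rose (11 up and 1 down of 21, 11 and 1 by list, mean 0.68, adjusted p = 3.9e-06). Among them Ifit2 rose by 3.11 ± 0.47 (n = 2 and 6), Bst2, which tethers budding viruses, 2.64 ± 0.19 (n = 3 and 3), and Zfp36 and Tnfaip3, brakes on inflammation, 2.70 ± 0.14 (n = 3 and 4) and 2.31 ± 0.17 (n = 2 and 6). Heat shock proteins rose (2 up and 1 down of 6, 2 and 1 by list, mean 0.81, adjusted p = 0.0098, 0.12 with an estimated correlation), with a mean of 0.42 and no call when outlier spots were kept. LPS lowered cholesterol and fatty acid genes (2 up and 10 down of 19, 2 and 10 by list, mean -0.74, adjusted p = 2.9e-07) and respiratory chain genes (14 of 23 down, 14 by list, mean -0.73, adjusted p = 2.4e-06). The fatty acid transporter Cd36 fell, at -2.15 ± 0.22 (n = 3 and 3), as did Cox7a2 of cytochrome oxidase, at -2.56 ± 0.30 (n = 3 and 4). Lysosome and macrophage identity genes fell (4 up and 9 down of 25, 4 and 9 by list, mean -0.45, adjusted p = 0.00033). Adgre1, the F4/80 antigen, fell, at -2.10 ± 0.21 (n = 3 and 5), but the Fc receptor Fcgr1 rose by 2.65 ± 0.36 (n = 2 and 5). Glycolysis and hypoxia genes fell (2 up and 11 down of 19, 2 and 11 by list, mean -0.50, adjusted p = 0.0038, 0.26 with an estimated correlation). Pdk1, which holds pyruvate back from mitochondria, fell, at -1.84 ± 0.16 (n = 3 and 3). Cell cycle genes fell (2 up and 17 down of 31, 2 and 19 by list, mean -0.78, adjusted p = 7.6e-06, 0.16 with an estimated correlation). The topoisomerase Top2a fell, at -2.30 ± 0.12 (adjusted p = 3.1e-10, n = 2 and 3). With media replicates 4 to 6 alone the means were -0.36 for cholesterol, -0.48 for the respiratory chain and -0.04 for cell cycle genes, and the first and last calls ended.

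Pattern receptors, endoplasmic reticulum stress and markers of other cell types had no call at 24 h of LPS (adjusted p 0.31, 0.79 and 0.055). Of the 21 markers 10 rose and 0 fell (adjusted p = 1.7e-06 with fry). Within these lists the RNA receptor Tlr7 fell, at -2.20 ± 0.19 (n = 3 and 5), the stress gene Ddit3 rose by 2.22 ± 0.14 and Des rose by 1.06 ± 0.16. LPS changed 6605 of 16826 genes at 24 h, 3639 up and 2966 down, while of those changed 2-fold or more 487 rose and 737 fell. LPS and media of 24 h shared no scan day, and 3350 genes were called with scan day as a random block. Against media replicates 4 to 6 alone 4048 were called.

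After 24 h poly(I:C) raised interferon-stimulated genes and lowered glycolysis genes, Csf1r and Igf1. Ifit2, which binds viral RNA, rose by 5.80 ± 0.41 (55.6-fold, adjusted p = 2.2e-09), with log2 ratios over the reference of 5.75 ± 1.70 against -0.04 ± 0.15 in media. Cmpk2 rose by 5.6 ± 0.34, Rsad2, which makes an antiviral nucleotide, 5.40 ± 0.52, Cxcl10 5.31 ± 0.39, Phf11a 5.04 ± 0.27 and Gbp2 4.79 ± 0.22 (n = 3 and 5). Without the departing array the log2 changes of Ifit2, Cmpk2, Rsad2 and Cxcl10 were 7.01, 6.61, 6.79 and 6.28. The largest falls were of Scd2 -3.57 ± 0.24 (n = 3 and 3), Csf1r -3.56 ± 0.12 (11.8-fold, adjusted p = 3.2e-16), the creatine enzyme Gatm -3.13 ± 0.16 (n = 3 and 4), the mitotic kinase Bub1 -3.08 ± 0.40 (n = 3 and 3) and the growth factor Igf1 -2.90 ± 0.17 (adjusted p = 8.4e-12). Bub1 stood at -1.99 when outlier spots were kept. Of the genes chosen beforehand, Irf7 rose by 3.73 ± 0.37 (adjusted p = 1.6e-07), Ccl5 3.01 ± 0.38 (adjusted p = 1.3e-06), Tnf 2.71 ± 0.48 (adjusted p = 0.00018, n = 3 and 2) and Nos2 2.60 ± 0.36 (adjusted p = 7.1e-06, n = 3 and 5). Ptgs2 rose by 2.41 ± 0.25 (adjusted p = 8.7e-07, n = 2 and 4), Il1b 0.87 ± 0.12 (adjusted p = 9.0e-06, n = 3 and 5) and Il6 0.77 ± 0.11 (adjusted p = 7.5e-06). Ptgs2 stood at log2 3.62 without the departing array and Il1b at 0.57 in the macrophage channel alone. Ifit1 had too few cultures and rose by 3.02 ± 0.19 with outlier spots kept.

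By gene list, poly(I:C) at 24 h raised interferon-stimulated genes (32 of 35 up, 33 by list, mean 2.54, adjusted p = 1.3e-41). Chemokines rose (11 of 15 up, 11 by list, mean 1.40, adjusted p = 3.9e-08), and so did NF-kB regulators (12 up and 1 down of 22, 13 and 1 by list, mean 0.84, adjusted p = 9.2e-08). Antigen presentation genes rose (16 up and 1 down of 22, 17 and 1 by list, mean 0.91, adjusted p = 2.1e-06). Cd274 rose by 2.19 ± 0.32 (n = 3 and 5) and B2m, the light chain of class I molecules, 1.91 ± 0.17 (n = 3 and 4). Effector enzymes rose (14 up and 1 down of 28, 14 and 1 by list, mean 0.68, adjusted p = 0.00053). So did apoptosis and survival genes (13 up and 2 down of 27, 13 and 4 by list, mean 0.56, adjusted p = 0.00031). Casp4, which senses LPS in the cytoplasm, rose by 2.77 ± 0.20 (n = 3 and 5). Inflammatory cytokines rose (13 up and 3 down of 22, 14 and 3 by list, mean 0.54, adjusted p = 0.012, 0.14 with an estimated correlation), with a mean of 0.22 and no call against media replicates 4 to 6 alone. Markers of other cell types rose (10 up and 1 down of 22, 10 and 1 by list, mean 0.37, adjusted p = 0.011, 0.058 with an estimated correlation). Des rose by 1.68 ± 0.16 and the keratin Krt18 1.37 ± 0.24 (n = 2 and 4).

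Poly(I:C) at 24 h lowered glycolysis genes (14 of 21 down, 15 by list, mean -0.93, adjusted p = 3.5e-09). Ldha, which makes lactate, fell, at -2.16 ± 0.20 (adjusted p = 1.8e-07, n = 3 and 3). Cholesterol genes fell (2 up and 16 down of 22, 2 and 17 by list, mean -0.89, adjusted p = 8.7e-08). Fdps of the sterol pathway fell, at -2.57 ± 0.12 (adjusted p = 5.5e-13, n = 3 and 4). Cell cycle genes fell (3 up and 21 down of 31, 3 and 21 by list, mean -1.06, adjusted p = 1.4e-08, 0.073 with an estimated correlation). Top2a fell, at -2.83 ± 0.10 (adjusted p = 3.0e-12, n = 3 and 3). Respiratory chain genes fell (1 up and 13 down of 25, 1 and 14 by list, mean -0.53, adjusted p = 0.00014, 0.1 with an estimated correlation). Ndufs1 of complex I fell, at -1.39 ± 0.18 (n = 3 and 3). Lysosome genes fell (5 up and 9 down of 26, 5 and 9 by list, mean -0.32, adjusted p = 0.0024). The integrin Itgb2 fell, at -2.11 ± 0.12, but without the departing array the mean was -0.06 and the call ended. Against media replicates 4 to 6 alone the means of cholesterol and cell cycle genes were -0.23 and -0.30 without calls. Poly(I:C) changed 8399 of 17768 genes at 24 h, 4823 up and 3576 down, of which 678 and 672 by 2-fold or more, and without the departing array 8116. A fit by Cy3 scan day, with media replicates 1 to 3, called 7555 genes, 6715 also in the same direction with all groups. It held the departing array, of another day.

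After 24 h CpG raised chemokines, endoplasmic reticulum stress genes and Lcn2. Lcn2 rose by 5.06 ± 0.33 (33.5-fold, adjusted p = 5.6e-10), with log2 ratios over the reference of 4.85 ± 0.09 against -0.22 ± 0.32 in media. Cxcl2 rose by 4.17 ± 0.28, Ptgs2 3.78 ± 0.22 (n = 3 and 4), Tnf 3.25 ± 0.48 (adjusted p = 0.0005, n = 3 and 2), Csf3 3.04 ± 0.18 and Sqstm1, a receptor of selective autophagy, 2.98 ± 0.34 (adjusted p = 5.8e-06). The monocyte chemokines Ccl7 and Ccl2 rose by 2.83 ± 0.10 (n = 3 and 3) and 2.63 ± 0.30 (n = 3 and 3), Il1b rose by 1.73 ± 0.12 (adjusted p = 1.8e-08, n = 3 and 5) and Il6 0.72 ± 0.11 (adjusted p = 0.00032). The largest falls were of Cysltr1 -1.76 ± 0.24 (3.38-fold, adjusted p = 9.8e-05, n = 3 and 3), the dynactin gene Actr1b -1.56 ± 0.26 (adjusted p = 0.00079, n = 3 and 4) and the chemokine receptor Cxcr4 -1.47 ± 0.28 (adjusted p = 0.0039, n = 2 and 3). Csf1r fell, at -1.29 ± 0.12 (adjusted p = 1.9e-07). Cxcl10 (0.22, adjusted p = 0.76), Ccl5 (-0.01, adjusted p = 0.98), Ifit1 (0.10, adjusted p = 0.6), Irf7 (1.0, adjusted p = 0.093) and Nos2 (0.66, adjusted p = 0.25) were not called. The scanner software ratio put Il6 at log2 2.5, and the authors' values put Cxcr4 at -0.89.

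By gene list, CpG at 24 h raised endoplasmic reticulum stress and amino acid response genes (10 of 16 up, 11 by list, mean 0.66, adjusted p = 8.3e-11). The chaperone Hspa5 rose by 2.03 ± 0.19 (adjusted p = 1.5e-05, n = 3 and 4), Ddit3 1.18 ± 0.14 (adjusted p = 6.1e-06) and the disulfide isomerase Pdia4 0.92 ± 0.15 (adjusted p = 0.00065, n = 3 and 5). It raised effector enzymes (10 of 28 up, 11 by list, mean 0.72, adjusted p = 6.8e-12). Chemokines rose (5 up and 0 down of 15, 5 and 1 by list, mean 0.93, adjusted p = 1.8e-11). So did NF-kB regulators (9 up and 0 down of 23, 9 and 1 by list, mean 0.47, adjusted p = 6.6e-10). Inflammatory cytokines rose (6 up and 1 down of 22, 7 and 2 by list, mean 0.53, adjusted p = 6.5e-08), and so did apoptosis genes (6 of 27 up, 7 by list, mean 0.26, adjusted p = 0.0043). Interferon-stimulated genes rose (4 up and 0 down of 39, 5 and 1 by list, mean 0.26, adjusted p = 0.0045, 0.41 with an estimated correlation). Immediate-early genes rose (2 up and 1 down of 18, 5 and 1 by list, mean 0.29, adjusted p = 0.027). Myc rose by 1.70 ± 0.33 (adjusted p = 0.0042, n = 3 and 3). The list call ended without media replicate 1 (0.26) and with media replicates 4 to 6 alone (-0.03). Respiratory chain genes rose (1 of 25 up, 1 by list, mean 0.26, adjusted p = 0.011, 0.3 with an estimated correlation). So did heat shock proteins (4 of 12 up, 5 by list, mean 0.40, adjusted p = 0.035, 0.14 with an estimated correlation). Without CpG replicates 1 or 2 these means were 0.15 and 0.18 for the respiratory chain and 0.22 and 0.21 for heat shock, none called, and the heat shock mean was -0.13 in the macrophage channel alone. Osteoclast genes fell (0 up and 1 down of 12, 1 and 6 by list, mean -0.23, adjusted p = 0.035, 0.061 with an estimated correlation), a call that ended without media replicate 2 (-0.21) or CpG replicate 1 (-0.17).

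Cell cycle genes had no call at 24 h of CpG (adjusted p = 0.36), but rose against media replicates 4 to 6 alone (mean 0.63, adjusted p = 6.7e-06). Tlr7 fell, at -1.25 ± 0.19 (adjusted p = 0.00047, n = 3 and 5), and Abcg1, at -1.21 ± 0.12 (n = 3 and 5). As a list, markers of other cell types had no call (adjusted p = 0.4). CpG changed 1785 of 17985 genes at 24 h, 947 up and 838 down, of which 193 and 47 by 2-fold or more. With scan day as a block, fitted to single arrays, 4462 genes were called. The count was 2838 within the shared scan day, 4318 with the authors' values and 499 in a fit of these 2 groups alone. It was 352 without CpG replicate 1, 472 without replicate 2 and 3421 without replicate 3. Of the 84 splits of these 9 cultures 2 gave at least as many genes, the highest being the split of media replicates 4 to 6 from the rest at 3089.

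**Figure D1:**
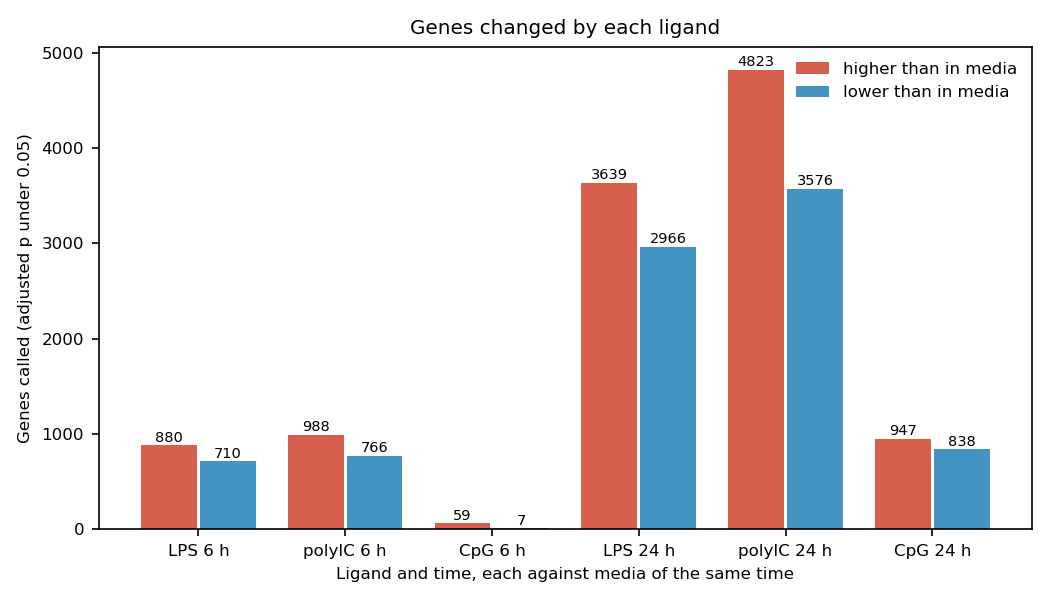
Number of genes called at adjusted p under 0.05 (vertical axis) higher and lower than in media of the same time, for each ligand and time (horizontal axis). CpG raised 59 and lowered 7 genes at 6 h, and poly(I:C) raised 4823 and lowered 3576 at 24 h.

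**Figure D2:**
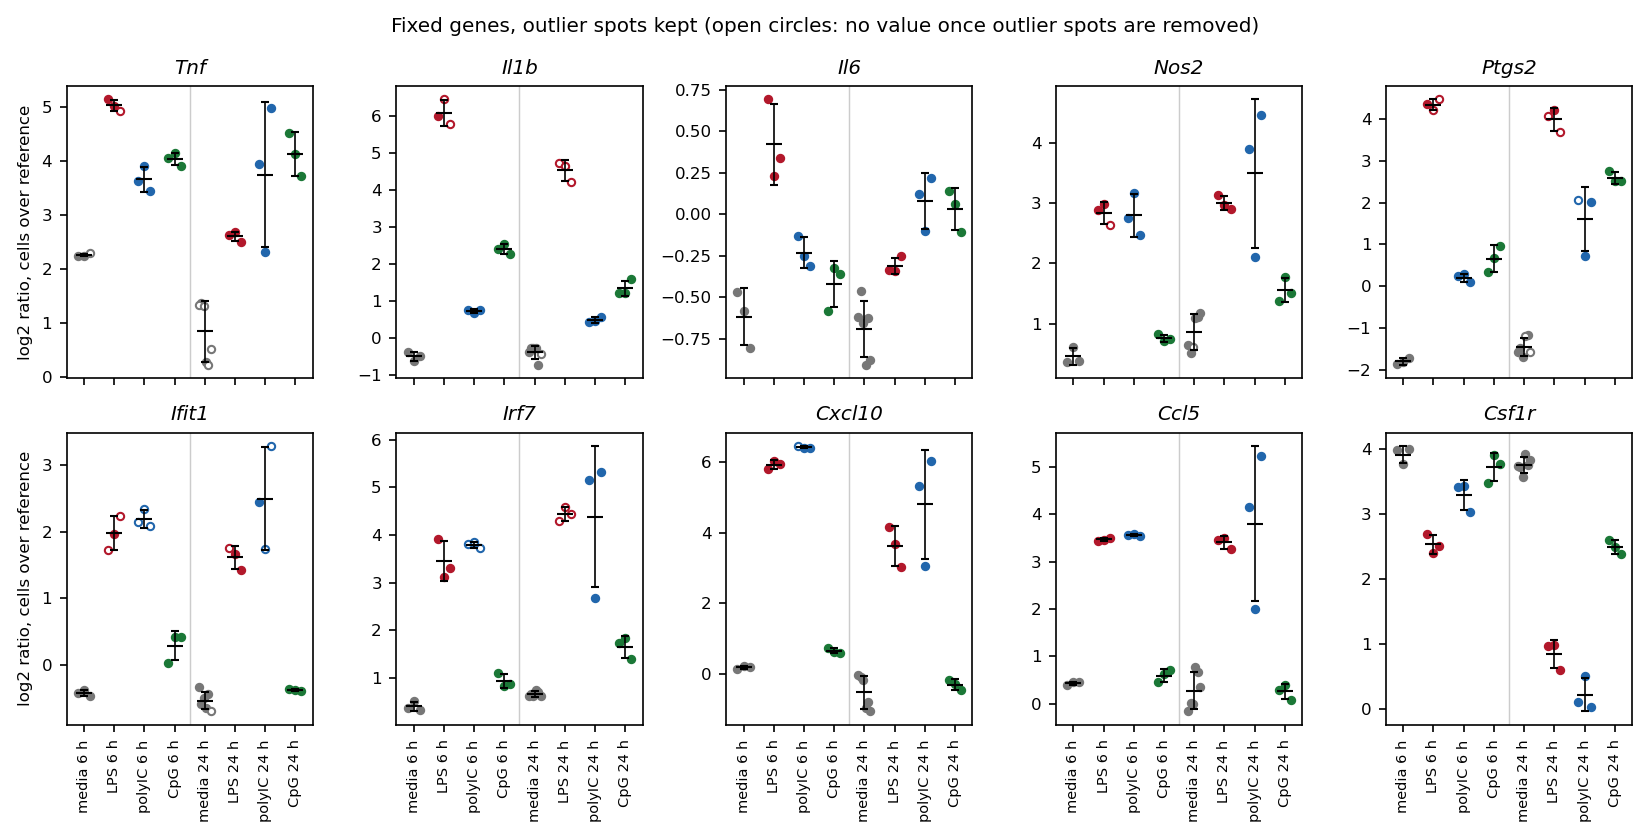
Log2 ratio of cells over reference RNA (vertical axis) in each culture of the 8 groups (horizontal axis), with mean ± SD, for the 10 genes chosen beforehand, with outlier spots kept and open circles for cultures without a value once they are removed. Csf1r lies 2.91 lower with LPS and 3.54 lower with poly(I:C) than in media at 24 h.

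Set directly against each other at 6 h, LPS exceeded poly(I:C) in cytokine genes. Csf3 was 5.74 ± 0.21 (adjusted p = 3.1e-15) higher with LPS, Il1a 4.30 ± 0.18, Il10 3.94 ± 0.16 and Saa3 3.22 ± 0.16. Poly(I:C) exceeded LPS in the sterol exporter Abcg1, at -2.16 ± 0.13 (adjusted p = 1.1e-10), in Zfp423, at -1.71 ± 0.17, and in the chemokine Cxcl9, at -1.65 ± 0.11. Cxcl9 stood well above background on none of the LPS arrays, so the difference was at least 2.29-fold. Cytokines were higher with LPS (6 up and 0 down of 20, 7 and 1 by list, mean 0.99, adjusted p = 1.7e-52), as were NF-kB regulators (7 of 20 up, 10 by list, mean 0.62, adjusted p = 1.9e-25). Interferon-stimulated genes were lower (3 of 20 down, 4 by list, mean -0.35, adjusted p = 0.00049, 0.27 with an estimated correlation), as were markers of other cell types (2 of 20 down, 4 by list, mean -0.27, adjusted p = 5.8e-06). Of 15517 genes 321 differed, 181 higher and 140 lower with LPS. Leaving out replicate 1 of LPS or of poly(I:C) gave 190 and 196, and a fit within the shared scan day called 322, of which 142 were higher and 180 lower with LPS. With scan day as a block 258 were higher and 292 lower.

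LPS exceeded CpG at 6 h in interferon genes and cytokines. Cxcl10 was 5.07 ± 0.46 (adjusted p = 5.0e-08) higher with LPS, Cmpk2 4.18 ± 0.40, Il1a 4.11 ± 0.18 and Csf3 3.98 ± 0.21. The urokinase Plau, at -2.06 ± 0.18 (n = 2 and 3), and Rasa3, at -1.79 ± 0.10, were lower. Interferon-stimulated genes were higher with LPS (21 of 25 up, 22 by list, mean 1.90, adjusted p = 1.7e-64), as were cytokines (9 of 21 up, 11 by list, mean 1.14, adjusted p = 5.6e-35) and chemokines (5 of 13 up, 7 by list, mean 1.65, adjusted p = 7.3e-34). Of 15995 genes 909 differed, 571 higher and 338 lower with LPS. With the authors' values 1408 genes differed, 50.5% of them higher against 62.8% here, and leaving out LPS replicate 2 gave 589.

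Poly(I:C) exceeded CpG at 6 h in interferon genes, and CpG exceeded poly(I:C) in a few inflammatory genes. Cxcl10 was 5.38 ± 0.51 (adjusted p = 7.2e-08, n = 2 and 3) higher with poly(I:C), Gbp2 4.74 ± 0.25, Ccl12 4.67 ± 0.12 and Ifit3 4.44 ± 0.25. Csf3, at -1.77 ± 0.21, Il1b, at -1.68 ± 0.13, and Cxcl2, at -1.58 ± 0.33 (adjusted p = 0.0022), were lower. Interferon-stimulated genes were higher with poly(I:C) (17 of 21 up, 20 by list, mean 2.04, adjusted p = 9.5e-62), as were chemokines (6 up and 1 down of 13, 6 and 1 by list, mean 1.40, adjusted p = 4.1e-31). Antigen presentation genes (8 of 18 up, 9 by list, mean 0.51, adjusted p = 0.00025) and markers of other cell types (6 of 21 up, 8 by list, mean 0.34, adjusted p = 0.00013) were also higher. The cytokine list was not called (adjusted p = 0.9). Of 16228 genes 1297 differed, 786 higher and 511 lower with poly(I:C). The higher share of 60.6% was 85.1% with scan day as a block (543 genes), 43.9% with the authors' values (2003 genes), 47.4% with median centring and 48.5% in the macrophage channel alone, and leaving out poly(I:C) replicate 1 gave 780.

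At 24 h LPS exceeded poly(I:C) in Saa3, Lcn2 and Csf3, and poly(I:C) exceeded LPS in interferon genes. Saa3 was 4.95 ± 0.16 (adjusted p = 3.3e-16) higher with LPS, Lcn2 4.44 ± 0.39 and Csf3 3.63 ± 0.21. Lower were Phf11a, at -4.89 ± 0.32 (adjusted p = 1.9e-10), Sqstm1, at -4.03 ± 0.40, and the GTPase Igtp, which acts on vacuoles of pathogens, at -3.69 ± 0.37. Interferon-stimulated genes were lower with LPS (2 up and 24 down of 31, 2 and 25 by list, mean -1.40, adjusted p = 1.8e-14), as were apoptosis genes (2 up and 10 down of 25, 2 and 10 by list, mean -0.43, adjusted p = 0.002). Of 16635 genes 6382 differed, 3161 higher and 3221 lower with LPS. The groups shared no scan day, and 2510 genes were called with scan day as a random block. With the authors' values 39.3% of the genes were higher, against 49.5% here.

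At 24 h LPS exceeded CpG in Saa3, Hspa1a and Cxcl10, and CpG exceeded LPS in respiratory chain and cholesterol genes. Saa3 was 4.40 ± 0.16 (adjusted p = 2.4e-15) higher with LPS, Hspa1a 4.19 ± 0.22 and Cxcl10 3.91 ± 0.46. Lower were Vim, at -4.64 ± 0.47 (adjusted p = 1.6e-07), Txnip, at -4.16 ± 0.34, and the elastase Mmp12, at -3.76 ± 0.47. Respiratory chain genes were lower with LPS (1 up and 18 down of 23, 1 and 20 by list, mean -0.99, adjusted p = 1.1e-08). So were cholesterol (1 up and 11 down of 19, 1 and 11 by list, mean -0.75, adjusted p = 7.1e-06) and lysosome genes (4 up and 10 down of 25, 4 and 10 by list, mean -0.62, adjusted p = 0.0018). Interferon-stimulated genes were higher (21 up and 2 down of 34, 21 and 3 by list, mean 0.75, adjusted p = 3.7e-05, 0.2 with an estimated correlation). Markers of other cell types were higher (8 of 21 up, 8 by list, mean 0.29, adjusted p = 0.017, 0.079 with an estimated correlation), and heat shock proteins had no call (adjusted p = 0.3). Of 16861 genes 7145 differed, 3958 higher and 3187 lower with LPS, while of those of 2-fold or more 481 were higher and 954 lower. The groups shared no scan day, and 3959 genes were called with scan day as a random block.

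At 24 h poly(I:C) exceeded CpG in interferon-stimulated genes, and CpG exceeded poly(I:C) in Lcn2 and in glycolysis, respiratory chain and cholesterol genes. Ifit2 was 5.6 ± 0.47 (adjusted p = 4.3e-08) higher with poly(I:C), Cmpk2 5.57 ± 0.40 and Cxcl10 5.09 ± 0.46. Lower were Lcn2, at -3.89 ± 0.39 (adjusted p = 4.9e-08), Ero1a, which oxidises proteins of the endoplasmic reticulum, at -3.64 ± 0.17, and Scd2, at -3.63 ± 0.24. Interferon-stimulated genes were higher with poly(I:C) (31 of 35 up, 31 by list, mean 2.27, adjusted p = 1.6e-30), as were antigen presentation genes (14 up and 1 down of 22, 14 and 1 by list, mean 0.76, adjusted p = 0.00013). So were markers of other cell types (10 of 22 up, 10 by list, mean 0.42, adjusted p = 0.0051). Lower were glycolysis (15 of 21 down, 15 by list, mean -1.11, adjusted p = 6.9e-10), respiratory chain (21 of 25 down, 22 by list, mean -0.79, adjusted p = 9.0e-07) and cholesterol genes (2 up and 15 down of 22, 3 and 15 by list, mean -0.88, adjusted p = 5.4e-07). Of 17822 genes 7930 differed, 4549 higher and 3381 lower with poly(I:C), while of those of 2-fold or more 604 were higher and 802 lower. A fit by Cy3 scan day, the departing array included, called 8682 genes, 7360 also in the same direction with all groups.

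The response to LPS was compared between times as the change at 24 h minus the change at 6 h, each against its own media. The response of Hspa1a grew by 4.19 ± 0.30 (adjusted p = 2.7e-09). Lower at 24 h were the responses of Ifih1, a sensor of viral RNA, at -3.62 ± 0.23 (adjusted p = 2.0e-09), Ccl22, at -3.60 ± 0.16 (adjusted p = 3.0e-13), and Ccl3, at -4.57 ± 1.0 (adjusted p = 0.0029). Vim moved down at -4.00 ± 0.63 (adjusted p = 0.00011), and Capn5 and Pou1f1 up by 3.33 ± 0.77 and 3.3 ± 0.77, but at -0.75 and -0.65 in the macrophage channel alone. Interferon-stimulated genes had lower responses at 24 h (2 up and 17 down of 24, 2 and 18 by list, mean -1.16, adjusted p = 8.2e-11, 0.038 with an estimated correlation). So had cytokines (7 of 20 down, 8 by list, mean -0.67, adjusted p = 6.4e-06). Chemokines were lower (5 of 13 down, 6 by list, mean -1.21, adjusted p = 6.4e-06), as were NF-kB regulators (7 of 20 down, 7 by list, mean -0.59, adjusted p = 2.0e-05). Pattern receptors (2 up and 6 down of 21, 4 and 7 by list, mean -0.55, adjusted p = 0.0047) and lysosome genes (8 of 20 down, 9 by list, mean -0.76, adjusted p = 7.3e-06) were lower too. With culture values from both arrays only the calls ended for chemokines (-0.78), NF-kB regulators (-0.58) and pattern receptors (-0.19), and with the authors' values for chemokines (-0.31). With 1 dye orientation they ended for NF-kB regulators (cells in Cy3, -0.31), chemokines and pattern receptors (cells in Cy5, -1.05 and -0.32). With probes well above background on all arrays the chemokine call ended (-1.24). Of 15318 genes 2908 differed, 1476 up and 1432 down, while of those of 2-fold or more 310 were up and 627 down. Leaving out LPS replicate 3 of 24 or of 6 h gave 1884 and 1923. LPS and media of 24 h shared no scan day, and 2026 genes were called with scan day as a random block.

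The response to poly(I:C) also differed between times. The response of Rnf19a, a ubiquitin ligase, grew by 3.86 ± 0.48 (adjusted p = 5.9e-06), and the fall of Csf1r deepened, at -3.02 ± 0.18 (adjusted p = 1.6e-10). Ccl12, at -2.86 ± 0.16 (adjusted p = 2.9e-11), and Cysltr1, at -2.81 ± 0.33, moved down. With the authors' values Ccl12 stood at -0.92 without a call. Lower responses at 24 h were found for chemokines (1 up and 5 down of 13, 2 and 5 by list, mean -0.74, adjusted p = 0.0003), cholesterol (1 up and 6 down of 15, 1 and 6 by list, mean -0.59, adjusted p = 0.0016) and lysosome genes (4 of 22 down, 4 by list, mean -0.52, adjusted p = 0.0019). The chemokine difference was 0.35 with the authors' values, -0.63 with the scanner software ratio, -0.45 among probes well above background on all arrays and -0.11 with outlier spots kept and the departing array left out, none called. Without the departing array chemokines stood at -0.38 and lysosome genes at -0.26, both called. Against media replicates 4 to 6 alone the cholesterol call ended (-0.23), and without poly(I:C) replicate 1 of 6 h the lysosome call (-0.41). With the cells in Cy5 alone the calls of both ended (-0.43 and -0.41), and with culture values from both arrays only those of all 3 lists (-0.80, -0.51 and -0.31). Interferon-stimulated genes had no called difference (adjusted p = 0.86). This stays open, as the departing array lowered Ifit2, Rsad2 and Cxcl10 at 24 h. Of 15541 genes 4341 differed, 2398 up and 1943 down. The share up of 55.2% was 70.1% with the authors' values, 46.2% in the macrophage channel alone and 40.2% with scan day as a block (1359 genes).

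The response to CpG grew with time in a few genes. Lcn2 grew by 4.75 ± 0.51 (adjusted p = 1.4e-05), Ccl7 3.01 ± 0.14 (adjusted p = 4.8e-08), Sqstm1 2.91 ± 0.53 (adjusted p = 0.0076) and the secreted Wfdc18 2.42 ± 0.35 (adjusted p = 0.0013). The cytokine Osm, which acts through gp130, moved down at -1.51 ± 0.32 (adjusted p = 0.025). Endoplasmic reticulum stress genes had a higher response at 24 h (2 of 15 up, 6 by list, mean 0.54, adjusted p = 2.0e-05), as did chemokines (1 up and 0 down of 15, 2 and 1 by list, mean 0.22, adjusted p = 0.0014). The chemokine call ended with scan day as a block (0.20), with the authors' values (0.02), with the cells in Cy3 alone (0.15), against media replicates 4 to 6 alone (0.000266) and among genes measured in all 8 groups (0.03). Interferon-stimulated genes showed no called difference (adjusted p = 0.79). Of 17218 genes 161 differed, 63 up and 98 down, and without CpG replicates 1, 2 or 3 of 24 h 33, 38 and 1263. Without media replicates 1, 2 or 3 of 6 h the counts were 65, 74 and 76, without CpG replicates 1 or 2 of 6 h 94 and 77, and without media replicate 5 of 24 h 104. With scan day as a block, fitted to single arrays, 2126 genes differed, 1078 up and 1048 down, and against media replicates 4 to 6 alone 1492. Of 100 drawn splits, which took no account of scan day, 16 gave at least 161 genes, so chance is not excluded.

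In media alone genes moved between 6 and 24 h. Vim rose by 3.22 ± 0.41 (adjusted p = 6.4e-06), the ribosomal genes Rps27a and Rps27 3.16 ± 0.50 (n = 4 and 3) and 2.64 ± 0.35 (n = 5 and 3), Ccl3 3.09 ± 0.62 (adjusted p = 0.00086) and the tetraspanin Cd9 2.99 ± 0.40 (n = 4 and 2). The anion transporter Slc26a11 fell, at -3.27 ± 0.46 (adjusted p = 9.4e-05, n = 5 and 3), as did the homeobox gene Cux2, at -2.70 ± 0.22 (n = 3 and 2). Pou1f1 and Capn5 fell, at -2.95 ± 0.49 (n = 4 and 3) and -2.74 ± 0.50, but stood at 1.04 and 0.78 in the macrophage channel alone. Lysosome and macrophage identity genes rose (10 up and 1 down of 26, 11 and 1 by list, mean 0.59, adjusted p = 0.00036). Of 17561 genes 4731 differed, 2348 up and 2383 down, and 491 by 2-fold or more. The media groups shared no scan day, and 1318 genes were called with scan day as a random block. With the authors' values 36.4% rose, against 49.6% here, and leaving out media replicate 3 or 2 of 6 h gave 2981 and 3042.

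**Figure D3:**
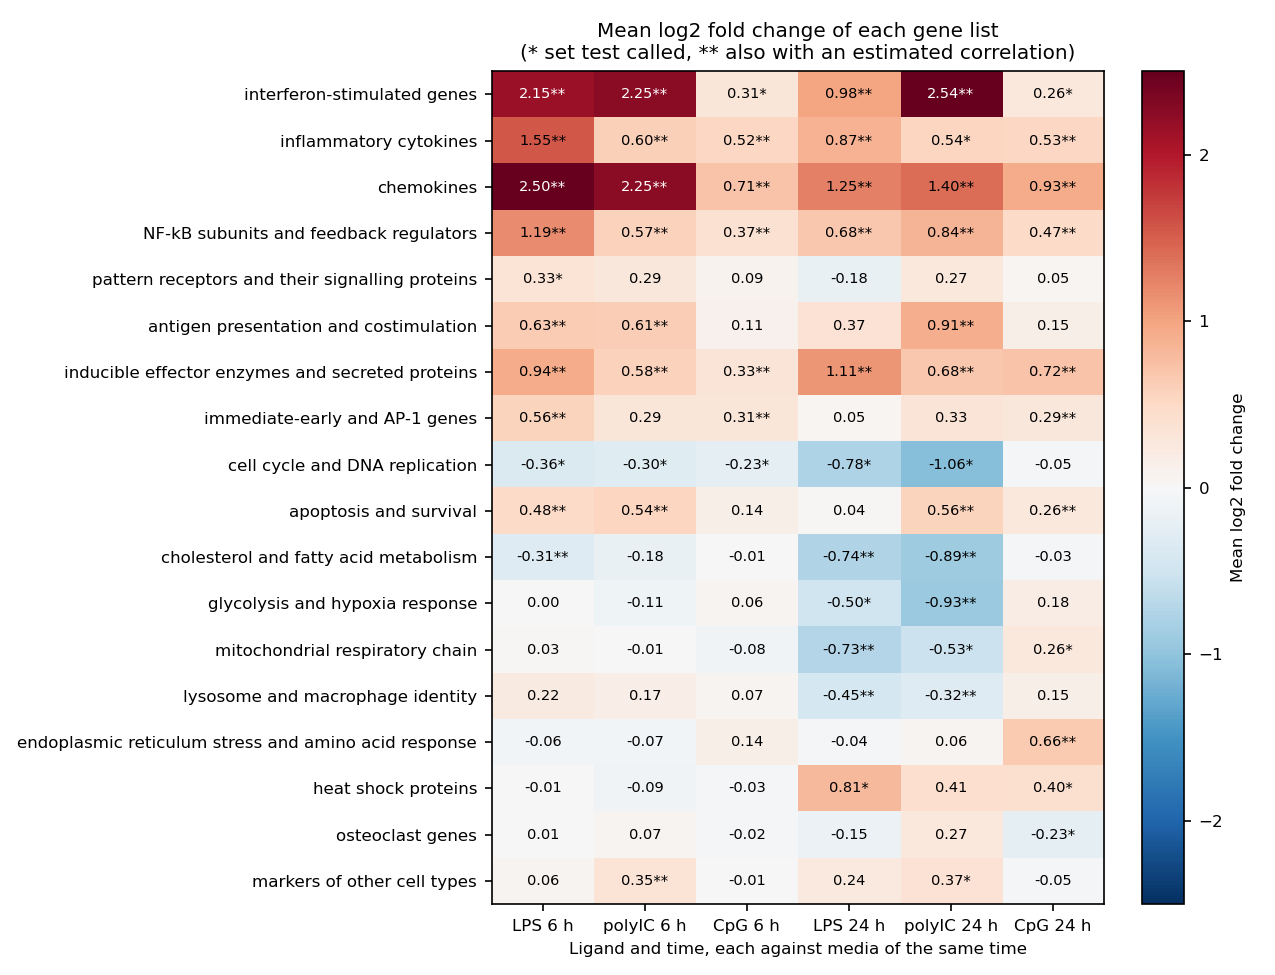
Mean log2 fold change (colour) of 18 gene lists (vertical axis) against media of the same time, by ligand and time (horizontal axis), with set tests called marked by 1 star and those also called with an estimated correlation by 2. Interferon-stimulated genes stood at 2.15 and 2.25 with LPS and poly(I:C) at 6 h and at 0.31 with CpG.

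Changes with LPS and poly(I:C) had their highest correlation at 6 h, where Cxcl10, Usp18 and Ifit3 rose with both. Of 15271 genes tested with both ligands, 553 rose in both comparisons where 50.3 would by independence, 406 fell in both where 32.1 would, and 4 moved in opposite directions. The log2 changes had a correlation of 0.833, against 0.498 in simulated unchanged groups that share their media cultures, and a covariance of 0.14, against 0.0149. All poly(I:C) and 4 of 6 LPS arrays of 6 h were scanned on another day than media, which the simulation leaves out. In a fit with scan day as a block the correlation was 0.842. Both changes there rest on the 1 LPS culture scanned with media, so scan day stays open. LPS and CpG shared 33 rises and 7 falls, where independence gives 2.17 and 0.314, with a correlation of 0.560 (0.499 simulated) and a covariance of 0.0465 (0.015). Poly(I:C) and CpG shared 25 and 6, where independence gives 2.72 and 0.335, with 0.447 (0.504) and 0.0372 (0.015). In the blocked fit LPS and CpG shared 213 rises and 79 falls and poly(I:C) and CpG 110 and 38, with correlations of 0.582 and 0.452. Genes are not independent replicates in these correlations.

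At 24 h Csf1r fell and Zfp36 and Csf3 rose with all 3 ligands. LPS and poly(I:C) raised 1649 genes together and lowered 1565, where independence gives 931 and 604, and 476 moved in opposite directions. LPS and CpG shared 267 rises and 284 falls (191 and 142), with 289 opposite, and poly(I:C) and CpG 361 and 345 (250 and 166), with 248 opposite. The correlations of log2 changes were 0.529, 0.122 and 0.256 for these pairs, against 0.38, 0.377 and 0.386 in simulated unchanged groups, and the covariances 0.172, 0.0222 and 0.05, against 0.0092, 0.00921 and 0.00955. With each ligand set against a different set of 3 media cultures, the pairs gave 0.204 and 0.545, -0.225 and 0.195, and 0.0806 and 0.133. In a fit with scan day as a block poly(I:C) and CpG shared 805 rises and 607 falls, with 768 opposite and a correlation of 0.215. With the different media sets opposite changes were 1061 and 173 for LPS and poly(I:C), 1178 and 73 for LPS and CpG, and 583 and 146 for poly(I:C) and CpG.

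**Figure D4:**
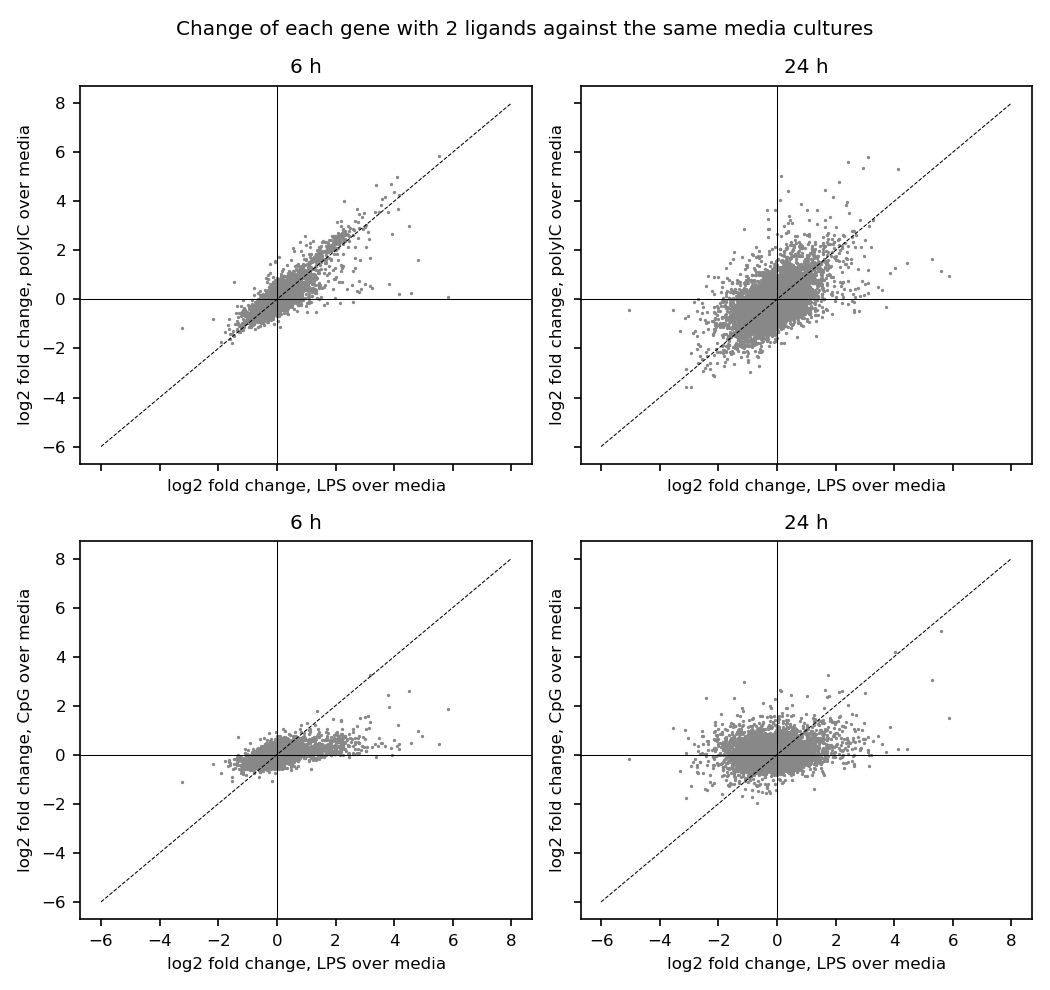
Log2 fold change of each gene over media with LPS (horizontal axis) against poly(I:C) (upper panels) and CpG (lower panels), at 6 h (left) and 24 h (right), with the line of equality dashed. The correlation was 0.833 for LPS and poly(I:C) at 6 h and 0.122 for LPS and CpG at 24 h.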

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

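These values were picked by rules set before the data were examined. In media at 24 h the mean log2 ratio of the endoplasmic reticulum stress list was 0.419 in replicate 6 and 0.529 to 0.579 in the other cultures, and its distance from the next, as a share of the range, was 0.686. It was 1 of 23 values so tested, and chance alone gives about 1 in 20. Responses differed between times in 2908 genes for LPS, 4341 for poly(I:C) and 161 for CpG. With LPS the list responses at 24 h minus 6 h were -1.16 for interferon genes, -0.673 for cytokines and -1.21 for chemokines. They were -0.592 for NF-kB regulators, -0.549 for pattern receptors and -0.761 for lysosome genes. With poly(I:C) they were -0.737 for chemokines, -0.589 for cholesterol and -0.523 for lysosome genes. With CpG they were 0.218 for chemokines, with a median of 0.00357, and 0.535 for endoplasmic reticulum stress. Over all these lists adjusted p was 0.0022 to 0.039 with an estimated correlation. The chemokine calls ended with the authors' values (-0.309, 0.346 and 0.0161 for the 3 ligands), and against media replicates 4 to 6 alone those of cholesterol with poly(I:C) (-0.227) and chemokines with CpG (0.000266) ended. These differences carry the day of scanning, which for LPS at 24 h and media cannot be separated from treatment, and no biological explanation was tested.

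The tests of reference RNA and of a swap were chosen after the result had been seen. On 1 array of poly(I:C) replicate 2 at 24 h, with the cells in Cy5, the log ratios had a correlation of 0.117 with those of its dye-swap partner. The cell channel of that array correlated at 0.887 with the median reference channel and at 0.848 with its own group, a difference of 0.0395, and the slope of its log ratios on those of its group was 0.154, against 0.783 to 1.16 on the other 53 arrays. Against reference RNA in both channels, 0.887 lay within the 0.855 to 0.929 of the other cell channels and below the lowest reference channel (0.94). Poorly labelled reference RNA could still give such a value, and no array shows what value it would have, so this stays open. Its cell channel correlated more with another group (0.869) than with its own. Its log ratios reached at most 0.191 with another group, where every other array reached 0.831 or more with its own, a difference of -0.64. They reached 0.169 with its own group, so a swap is excluded only if the array worked. Poor hybridisation of the whole array stays open, as its reference channel ranked 3 from the lowest of 54 arrays, at 0.946 against a median of 0.988.

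The tests of the media sets were written before they were run. Media replicates 1 to 3 and 4 to 6 of 24 h differed in 2319 genes, 1145 higher and 1174 lower in the first set. They were scanned on different days with different scanners. The reference channel, which held the same RNA, gave 1253 called genes against 1880 in the macrophage channel, a ratio of 0.666, so scanning or hybridisation may account for much of the difference. A single deviating culture is excluded, as the lowest count without 1 culture was 0.558 of the full count. No biological explanation was tested.

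The test of the departing array as a cause was chosen after the result had been seen, and that of scanning before. LPS and poly(I:C) differed in 321 genes at 6 h and in 6382 at 24 h. The groups shared a scan day only at 6 h, so scanning or hybridisation stays open. The reference channel gave 1641 called genes against 5734 in the macrophage channel at 24 h, a ratio of 0.286. It gave 2 against 334 at 6 h. Without the departing array the count at 24 h was still 16 times that at 6 h, so that array is excluded as the cause. No biological explanation was tested.

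Chance was tested by splitting the same cultures in other ways, which took no account of scan day and exclude nothing about it. With 3 against 3 there are 10 splits, too few for a share under 0.05. Only the real split, 1 of 10, reached its count for LPS at 6 h (1590, highest other 5), poly(I:C) at 6 h (1754 and 7), LPS against poly(I:C) at 6 h (321 and 7) and 24 h (6382 and 35), LPS against CpG at 6 h (909 and 5) and 24 h (7145 and 137), and poly(I:C) against CpG at 6 h (1297 and 1) and 24 h (7930 and 506). For CpG at 6 h 2 of 10 did (66, highest other 107). Of 84 splits 1 reached the count for LPS at 24 h (6605, highest other 4276), for poly(I:C) at 24 h (8399 and 3588) and for media over time (4731 and 2905), so chance can be excluded there. For CpG at 24 h 2 of 84 did. The other, with 3089 against 1785, parted media replicates 4 to 6, which had a scan day of their own, from the rest. Chance can be excluded there but not an effect of scan day, and 4462 genes were called with scan day as a block and 2838 within the shared day. Of 100 drawn splits 3 reached the count of the LPS time difference (2908, highest other 4067) and 3 that of poly(I:C) (4341 and 6607). These splits move cultures between times, so they cannot exclude chance. In the highest others all media of 6 h changed places with 3 media of 24 h. With scan day as a random block 2026 genes were called for LPS, and as a fixed block 1359 for poly(I:C). For CpG 16 did (161 and 5569, 2126 with the fixed block), so chance cannot be excluded.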

How the results depend on the processing

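Of 14373 results for named genes under alternative settings 13480 stayed as reported, 851 were weaker, 30 stronger and 12 reversed, and of the 493 pairs of gene and comparison 320 never changed. Of 4092 results for gene lists 3808 stayed, 204 were weaker, 73 stronger and 7 reversed, and of 129 pairs of list and comparison 60 never changed. Counts that moved more than 1.5 times follow by setting, and the cause was not tested unless fewer cultures or a stricter threshold made it plain. Scan day could not be fitted as a fixed block where LPS at 24 h met media or another ligand of 24 h, in the LPS time difference or for media over time, since no other group linked their days. Quantile normalisation of the average signal left every ratio unchanged and is not in these numbers. Thresholds aside, the share of genes higher crossed 50% in other settings for LPS against poly(I:C) at 24 h (to 54.3%) and 6 h (to 46.5%). So it did for the LPS (to 45.2%) and CpG time differences (to 53.6%), media over time (to 54.7%) and CpG at 24 h (to 47.8%). The replicate numbers did not pair cultures: 19 of 84 pairs of equal number had a residual correlation over 0.1 (-0.423 to 0.438, median -0.022, 7184 genes), and 6 of 24 cultures lay closest to their own number. The correlation within a culture was 0.0468 in the fit of single arrays, and within a scan day 0.396. Leave-one-out gave 1085 to 1258 for LPS at 6 h, 4479 to 6766 for LPS at 24 h, 1106 to 1374 for poly(I:C) at 6 h, 6862 to 8139 for poly(I:C) at 24 h, 31 to 55 for CpG at 6 h, 352 to 3421 for CpG at 24 h, 190 to 248 for LPS against poly(I:C) at 6 h, 4639 to 5557 for LPS against poly(I:C) at 24 h, 589 to 743 for LPS against CpG at 6 h, 5142 to 7451 for LPS against CpG at 24 h, 780 to 1124 for poly(I:C) against CpG at 6 h, 5808 to 8063 for poly(I:C) against CpG at 24 h, 1884 to 3079 for the LPS time difference, 3207 to 4251 for the poly(I:C) time difference, 33 to 1263 for the CpG time difference and 2981 to 4548 for media over time. Where this left 1 culture in a group, it was assumed to vary like the others.

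Among changes of 2-fold or more the counts were 456 for LPS at 6 h, 1224 for LPS at 24 h, 405 for poly(I:C) at 6 h, 1350 for poly(I:C) at 24 h, 22 for CpG at 6 h, 240 for CpG at 24 h, 73 for LPS against poly(I:C) at 6 h, 1050 for LPS against poly(I:C) at 24 h, 322 for LPS against CpG at 6 h, 1435 for LPS against CpG at 24 h, 338 for poly(I:C) against CpG at 6 h, 1406 for poly(I:C) against CpG at 24 h, 937 for the LPS time difference, 968 for the poly(I:C) time difference, 69 for the CpG time difference and 491 for media over time. At adjusted p under 0.01 they were 984 for LPS at 6 h, 988 for poly(I:C) at 6 h, 32 for CpG at 6 h, 540 for CpG at 24 h, 187 for LPS against poly(I:C) at 6 h, 4126 for LPS against poly(I:C) at 24 h, 553 for LPS against CpG at 6 h, 736 for poly(I:C) against CpG at 6 h, 1435 for the LPS time difference, 2186 for the poly(I:C) time difference, 31 for the CpG time difference and 2563 for media over time. The authors' values gave 4318 for CpG at 24 h, 1408 for LPS against CpG at 6 h, 2003 for poly(I:C) against CpG at 6 h and 389 for the CpG time difference, and median centring without loess gave 35 for the CpG time difference, with Ciita at 0.0698 for CpG at 24 h. Arrays with the cells in Cy3 alone gave 932 for LPS at 6 h, 142 for LPS against poly(I:C) at 6 h, 4216 for LPS against poly(I:C) at 24 h, 4749 for LPS against CpG at 24 h, 1835 for the LPS time difference, 2204 for the poly(I:C) time difference and 96 for the CpG time difference. Arrays with the cells in Cy5 alone gave 955 for LPS at 6 h, 20 for CpG at 6 h, 419 for CpG at 24 h, 130 for LPS against poly(I:C) at 6 h, 1187 for the LPS time difference, 2164 for the poly(I:C) time difference and 34 for the CpG time difference, with Ctsl at -0.34 for poly(I:C) at 24 h. The macrophage channel alone gave 1979 for poly(I:C) against CpG at 6 h, 4830 for poly(I:C) against CpG at 24 h, 2087 for the poly(I:C) time difference and 56 for the CpG time difference. In that channel the sign reversed for Capn5 and Pou1f1 in the LPS time difference (-0.75 and -0.65) and in media over time (0.78 and 1.04). It also reversed for Egr2 in LPS vs media at 24 h (-0.0948) and H2-Q7 in LPS vs media at 24 h (-0.0537). With CpG at 24 h it reversed for Dnajb1 (-0.32), Hspa1b (-0.10) and the heat shock list (-0.13), and for Ticam2 in CpG vs media at 24 h (-0.0904). With the mean of all probes of a gene Uqcrc2 stood at 0.14 for LPS at 6 h. A fit of only the groups of each comparison gave 30 for CpG at 6 h, 499 for CpG at 24 h and 76 for the CpG time difference, a replicate block 845 for CpG at 24 h and 92 for the CpG time difference, and a fit of single arrays 334 for the CpG time difference. With scan day as a block the counts were 732 for poly(I:C) at 6 h, 472 for CpG at 6 h, 4462 for CpG at 24 h, 550 for LPS against poly(I:C) at 6 h, 543 for poly(I:C) against CpG at 6 h, 1359 for the poly(I:C) time difference and 2126 for the CpG time difference, and as a random block 3350 for LPS at 24 h, 2510 for LPS against poly(I:C) at 24 h, 3959 for LPS against CpG at 24 h and 1318 for media over time. Against media replicates 1 to 3 alone the count was 977 for CpG at 24 h. Against media replicates 4 to 6 alone it was 4048 for LPS at 24 h, 3167 for CpG at 24 h and 1492 for the CpG time difference, with cell cycle genes at 0.63 for CpG at 24 h, and immediate-early and AP-1 genes in CpG vs media at 24 h at -0.0292. Genes called in the same direction at 24 h with different media sets for each ligand were 1615 and 1898 for LPS and poly(I:C), against 3214, 447 and 234 for LPS and CpG, against 551, and 709 and 221 for poly(I:C) and CpG, against 706.

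The settings that follow were chosen after the data had been seen. With outlier spots kept the counts were 2621 for LPS at 6 h, 2781 for poly(I:C) at 6 h, 103 for CpG at 6 h, 3239 for CpG at 24 h, 560 for LPS against poly(I:C) at 6 h, 1579 for LPS against CpG at 6 h, 2161 for poly(I:C) against CpG at 6 h, 5052 for the LPS time difference, 7308 for the poly(I:C) time difference and 366 for the CpG time difference. With the departing array left out they were 128 for CpG at 6 h and 299 for the CpG time difference. With both changes they were 2974 for LPS at 6 h, 3139 for poly(I:C) at 6 h, 187 for CpG at 6 h, 3925 for CpG at 24 h, 701 for LPS against poly(I:C) at 6 h, 1881 for LPS against CpG at 6 h, 2555 for poly(I:C) against CpG at 6 h, 5639 for the LPS time difference, 7326 for the poly(I:C) time difference, 617 for the CpG time difference and 7177 for media over time. With culture values from both arrays only they were 967 for LPS at 6 h, 1004 for poly(I:C) at 6 h, 201 for LPS against poly(I:C) at 6 h, 828 for poly(I:C) against CpG at 6 h, 1732 for the LPS time difference and 2277 for the poly(I:C) time difference, and among genes measured in all 8 groups 38 for CpG at 6 h and 87 for the CpG time difference. The lists of the time differences were run under all settings after their calls had been seen. The mean reversed without a call for chemokines (0.346 for poly(I:C) with the authors' values) and heat shock proteins (-0.116 for CpG in the macrophage channel alone). Against media replicates 4 to 6 alone it shrank without a call for chemokines (CpG, 0.000266) and cell cycle genes (poly(I:C), -0.016). Fits within 1 scan day gave 234 genes for CpG at 6 h and 2838 for CpG at 24 h.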

Other observations

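Metabolic gene lists differed between ligands at 24 h. Glycolysis genes had a mean log2 change of -0.50 with LPS and -0.93 with poly(I:C), and of 0.18 with CpG (adjusted p 0.26, 0.018 and 0.78 with an estimated correlation). Respiratory chain genes stood at -0.73, -0.53 and 0.26 (0.029, 0.1 and 0.3), and cholesterol and fatty acid genes at -0.74, -0.89 and -0.03. The cholesterol calls with LPS and poly(I:C) ended against media replicates 4 to 6 alone. In the direct tests at 24 h poly(I:C) lay below CpG in glycolysis genes by a mean of -1.11 (adjusted p = 6.9e-10) and LPS below CpG in respiratory chain genes by -0.99 (adjusted p = 1.1e-08). Osteoclast genes showed no list call with LPS or poly(I:C), although Ctsk, a bone-degrading protease, fell by 0.93 with LPS at 24 h and Mitf, a driver of that programme, rose by 1.47 with poly(I:C). Median, mean and test of a list differed in sign among called lists only in LPS against poly(I:C) at 6 h, for immediate-early genes (median -0.000529, mean 0.30) and cholesterol genes (0.02 and -0.15).

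The following test was chosen after the result had been seen. CpG at 6 h raised cytokines as a list but few single interferon-stimulated genes were called, and a weaker copy of the LPS response could look so. The mean CpG change was 0.404 for 21 cytokines, where LPS gave 1.55, and 0.248 for 25 interferon-stimulated genes, where LPS gave 2.15. The ratios were 0.261 and 0.115, and their difference of 0.146 had a bootstrap 95% interval over genes of 0.0233 to 0.279. The 95% interval between cultures was 0.106 to 0.186, and without 1 culture the difference was 0.0999 to 0.156. This argues against 1 common factor for these genes, scan day aside. With outlier spots kept the difference was 0.196 (0.0792 to 0.31). Genes are not independent replicates, and the idea that CpG may spare the interferon branch came from the same data.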
